A study of Mus musculus with 33 samples.

How the data were processed

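Total RNA of mouse liver tissue was isolated with the mirVana kit and labelled as biotinylated cRNA with the Illumina TotalPrep kit, per the labels' protocols. The cRNA was hybridised to Illumina MouseWG-6 v2.0 bead arrays with 45281 probes, one array per sample. BeadStudio, whose version is not given in the sources used here, is named in the submitters' processing notes. The authors deposited linear probe intensity values (BeadStudio signals) for all 33 arrays, with no detection p-value beside them, and a matrix of log2 values for the same arrays. The authors' log2 values were found to equal quantile-normalized signals without background correction, to within 0.00546, with no centring of genes and no change of direction; the median of each column of that matrix was 6.57.

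Samples were assigned to 7 groups by the genotype and tissue in the labels: tumour and surrounding liver of Sav1 knockout mice (11 and 7 arrays), tumour and surrounding liver of Mst1/2 knockout mice (4 and 3), and normal livers of Sav1 floxed (3), Mst1/2 floxed (3) and wild-type mice (2). Replicate numbers were those of the labels. No pair of arrays was a duplicate, since the highest correlation between any pair was 0.994. The estimated background thresholds ran from 81.7 to 109 signal units.

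The groups, comparisons, tests, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. The plan named limma's neqc, which infers negative controls from detection p-values, and normexp with an offset of 50 in their absence. As no detection p-values were present, the deposited signals were corrected with normexp at an offset of 50, quantile normalized between arrays and taken to log2 (floor 5.64). For the same reason a probe was called above background where its signal exceeded the 99th percentile of a background distribution made by mirroring the lower part of each array's signals about its mode. The 23254 probes above background on at least 3 arrays and assigned to 1 gene were kept. Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 several and 10378 none. Symbols of 34807 were matched through Entrez identifiers to the RefSeq genes of GRCm38.p6, and 0 were renamed. A gene was represented by its kept probe with the highest mean over all arrays, which gave 13997 genes, 5925 of which had more than 1 kept probe. Probes of 1 gene passed the test in opposite directions for 149, 18, 10, 0, 2 and 0 genes in the first 6 comparisons in the order of the report. Probes without a gene or with several were left out of gene tests.

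Levels were compared with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, in one fit with a mean per group over all 33 arrays, two-sided, with Benjamini-Hochberg adjustment over all genes in each comparison and a threshold of 0.05. Tumour and surrounding liver of each knockout were set against the floxed livers of the same line, tumour against surrounding liver within each line, the lines against each other within each tissue, and differences of these differences were tested as interaction terms. The normal livers were compared by a moderated F test, and floxed livers of the lines with each other. The 38 gene lists fixed in advance were tested with camera (preset correlation 0.01) in 8 comparisons, adjusted over the 35 lists with at least 5 tested members. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

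Genes named were, by the fixed rule, the targeted genes in every group; for each of the first 6 comparisons the 8 largest rises and 8 largest falls among changed genes above background on at least 1 array of each group and with no overlap between the groups' arrays, and the 4 largest in each direction among changed genes above background on every array of one group and on no array of the other; and the 5 largest terms in each direction for the other comparisons. List members and the Xist and Y-linked genes given as examples were chosen after their values were seen.

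Arrays were sorted into 3 sets by the correlation of their signals over 12527 probes above background on no array, after the data were seen; the mean correlation within sets A, B and C was 0.132, 0.0126 and 0.0274, against -0.0987, -0.0730 and -0.0339 with arrays of the other sets. Same-numbered samples were compared by correlating their deviations from group means. In Sav1 against Mst1/2 surrounding liver all 3 pairs exceeded 0.1 (0.184 to 0.339), the own number highest in 1. Numbers were taken as pairs there on that measure alone. No label links the lines, and mice of different genotypes cannot be 1 animal, so these are not matched samples.

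The steps were tested on simulated data made from the spread of the real arrays with known changes. Of 100 genes changed 2-fold, 71, 63, 63, 66, 90, 56, 80 and 70 were recovered in the first 8 comparisons in the order of the report and 43 between the floxed livers. Between 1 and 8 unchanged genes were called among the 13997 in each. Alternatives were other normalizations, background corrections, probe filters and probe choices, array weights, trended robust moderation, fits of the groups compared, other controls, array set and replicate blocks, other list tests, and leaving out each array of a comparison in turn.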

Results

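RNA of 33 mouse liver samples was measured on Illumina MouseWG-6 v2.0 bead arrays, one array per sample, in 7 groups. Tumours were hepatocellular carcinomas (HCC) from mice with knockout of Sav1 (n = 11) or of Mst1 and Mst2 together (n = 4). Surrounding liver of the same kinds of knockout mice gave 7 Sav1 and 3 Mst1/2 samples, and normal livers came from Sav1 floxed mice (n = 3), Mst1/2 floxed mice (n = 3) and wild-type mice (n = 2). Sav1 and the kinases Mst1 and Mst2 form the core of the Hippo pathway, which holds back the transcriptional coactivators YAP and TAZ. The labels do not say whether the replicates of a group were separate animals, so the p-values measure the spread between these samples, which may be partly technical. Median signals per array ran from 78.5 to 112 units, and 34.6% to 53.5% of the 45281 probes exceeded the array's estimated background. The number of arrays limits the precision. The 13997 genes with a probe above background on at least 3 arrays were tested. Changes are log2 differences ± standard error from limma after quantile normalization, and values in parentheses after a gene are such differences unless a fold is named. Genes that changed, rose or fell passed limma at a Benjamini-Hochberg adjusted p threshold of 0.05. Both p-values of a list are adjusted over lists, and where it has no count adjusted over the list alone, that count was the same.

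Sav1 transcript was measured by 1 probe, ILMN_2767596, and stood at 9.26 ± 0.33 (SD, n = 3) in Sav1 floxed livers, 9.12 ± 0.32 (n = 7) in Sav1 surrounding livers and 9.00 ± 0.49 (n = 11) in Sav1 tumours. The level was 8.86 ± 0.12 (n = 3) in Mst1/2 floxed livers, 9.04 ± 0.19 (n = 2) in wild-type livers, 8.98 ± 0.15 (n = 3) in Mst1/2 surrounding livers and 9.17 ± 0.32 (n = 4) in Mst1/2 tumours. The Sav1 tumours differed from their floxed livers by -0.26 ± 0.24, which did not pass (adjusted p = 0.41). The Stk4 (Mst1) probe, ILMN_3004142, stood at 9.64 ± 0.12 (n = 3) in Mst1/2 floxed livers, 9.80 ± 0.14 (n = 3) in Mst1/2 surrounding livers and 9.77 ± 0.17 (n = 4) in Mst1/2 tumours, with 9.85 ± 0.17 (n = 3), 9.81 ± 0.35 (n = 7) and 10.07 ± 0.54 (n = 11) in the Sav1 floxed livers, surrounding livers and tumours and 9.62 ± 0.02 (n = 2) in wild-type livers. Stk3 (Mst2) was not analysed here because no probe is listed for it. The position of these probes relative to the deleted exons is not given in the sources used here, so they check nothing about the knockouts.

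Xist, the X-inactivation transcript of female cells, stood at 10.87 ± 0.34 (SD, n = 3) in the Mst1/2 floxed livers, whereas the other 6 groups averaged 6.12 to 6.30. The Y-linked translation factor gene Eif2s3y stood at 6.10 ± 0.06 (n = 3) in the Mst1/2 floxed livers, against 11.43 ± 0.29 in Sav1 floxed livers (n = 3), 11.35 ± 0.26 (n = 7) and 11.27 ± 0.05 (n = 3) in Sav1 and Mst1/2 surrounding livers and 10.95 ± 0.26 (n = 4) in Mst1/2 tumours. The control livers of the Mst1/2 line thus carried a female pattern and the knockout samples of that line a male one. Wild-type livers had Eif2s3y at only 6.83 ± 0.20 (n = 2) but low Xist and Y-linked Kdm5d at 7.91 ± 0.54, which argues against females. Separately, the arrays fell into 3 sets by the pattern of signal over 12527 probes that exceeded background nowhere. Set A held 9 arrays (Sav1 floxed, surrounding and tumour samples 1 to 3), set C held 6 (Sav1 surrounding samples 4 to 7 and tumours 4 and 5) and set B held 18 (Sav1 tumours 6 to 11, all Mst1/2 samples and the wild-type livers). The labels name no such sets.

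**Figure D1:**
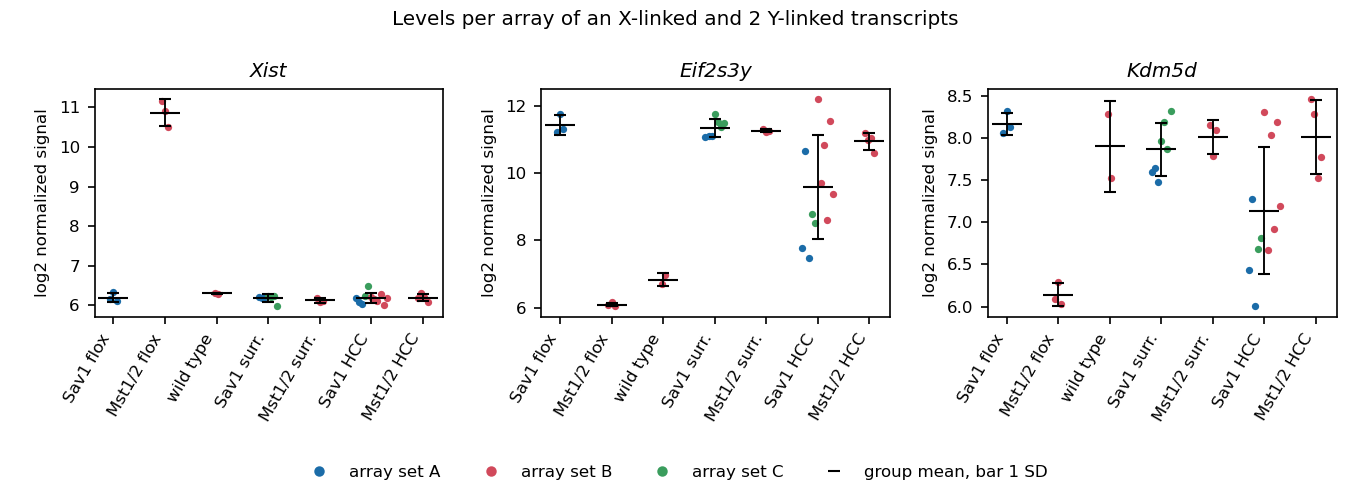
Log2 normalized signal of the X-linked transcript Xist and the Y-linked genes Eif2s3y and Kdm5d on the y axis, for each of the 33 arrays by group on the x axis; points are arrays coloured by array set, and bars show the group mean ± 1 SD. Xist is high in the 3 Mst1/2 floxed livers, whose mean is 10.87, and Eif2s3y spreads from 7.47 to 12.20 among the 11 Sav1 tumours.

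In Sav1 tumours (n = 11) against Sav1 floxed livers (n = 3), the MHC class II chains H2-Aa and H2-Eb1 rose 52.9-fold (log2 difference 5.73 ± 0.59, adjusted p = 1.0e-07) and 32.8-fold (log2 difference 5.04 ± 0.61, adjusted p = 8.6e-07). Lcn2, which encodes an iron-binding protein of neutrophils and injured epithelium, rose 48.6-fold (log2 difference 5.60 ± 0.65, adjusted p = 4.3e-07), and Gpc3, a glypican of fetal liver and liver cancer, rose 34.8-fold (log2 difference 5.12 ± 0.54, adjusted p = 1.3e-07). Spink1, a trypsin inhibitor gene above background in no floxed liver, rose at least 109.7-fold. Hsd3b5, a steroid dehydrogenase gene of male liver, fell 144-fold (log2 difference -7.17 ± 0.78, adjusted p = 1.7e-07), and Cyp2f2, a periportal cytochrome P450 gene, fell 75-fold (log2 difference -6.23 ± 1.08, adjusted p = 9.3e-05). In all, 4650 of 13997 genes changed, 2429 of them higher and 2221 lower, with at least 2-fold changes in 1167 and 747.

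Other large rises in the Sav1 tumours were those of S100a11 (5.10 ± 0.46), Espn (4.97 ± 0.60), Chrnb1 (4.91 ± 0.47) and Gdpd3 (4.72 ± 0.62); Espn bundles actin and S100a11 binds calcium. Genes above background in no floxed liver included Esm1 (at least 28.3-fold), Cib3 (at least 21.1-fold) and Psca (at least 12.3-fold), all higher. Such an "at least" fold sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest normalized signal among probes above background and the probe's own signal. Large falls were those of Sult2a8 (-5.29 ± 0.98), Hal (-4.74 ± 0.79), Elovl3 (-4.51 ± 0.37), Nlrp12 (-4.38 ± 0.42), Ces3b (-4.23 ± 1.05) and Cyp3a11 (-4.2 ± 1.12), where Hal starts histidine breakdown and Cyp3a11 oxidizes drugs. Cyp2b10 (at least 24.1-fold), Hectd2os (at least 12.9-fold), Cyp2b23 (at least 5.3-fold) and Tafa5 (at least 2.09-fold) were lower and above background in no tumour. Of the 58 changed genes named, 56 lay on the stated side of the floxed mean in all 11 arrays, and the others in at least 10. The choice of genes favours this throughout, so it is no test.

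Lists of growth and progenitor genes stood higher in the Sav1 tumours. Of the cell cycle genes, 28 of 34 rose and 6 did not pass (28 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.9e-08, p = 0.21 with estimated correlation). Rises included Ccnd1 (3.23 ± 0.48) and Stmn1 (3.14 ± 0.47). Of the YAP/TAZ target genes, 11 of 19 rose and 8 did not pass (12 rose adjusted over the list alone, camera adjusted p = 5.9e-05, p = 0.13 with estimated correlation). Rises included Amotl2 (1.09 ± 0.14) and Ccn2 (2.37 ± 0.43). Among biliary and progenitor cell markers 7 of 20 rose and 13 did not pass (camera adjusted p = 1.7e-04, p = 0.19 with estimated correlation). Rises included Sox4 (3.49 ± 0.40) and Sox9 (3.12 ± 0.56). Among fetal liver and tumour-associated genes, 8 of 17 rose and 9 did not pass (camera adjusted p = 0.0040, p = 0.21 with estimated correlation). Rises included Ly6d (at least 3.03-fold) and Pkm (1.66 ± 0.56). In the epithelial junction and cytoskeleton list 20 of 30 rose, 3 fell and 7 did not pass (21 rose and 3 fell adjusted over the list alone, camera higher, adjusted p = 2.7e-07, p = 0.13 with estimated correlation), with the annexin gene Anxa2 at 3.70 ± 0.37. Among ribosomal protein genes, 21 of 24 rose and 3 did not pass (camera adjusted p = 9.3e-09, p = 0.19 with estimated correlation). Of Hippo pathway components, 9 of 23 rose, 2 fell and 12 did not pass (camera higher, adjusted p = 0.063), though the list was called higher within array set A, with the set as a block, under median scaling and with the mean of the 3 normal groups as control. Among Notch pathway genes, 7 of 16 rose, 2 fell and 7 did not pass (camera higher, adjusted p = 0.13). Rises included Sox9 (3.12 ± 0.56) and Jag1 (2.73 ± 0.55). Among p53 target and DNA damage genes 6 of 16 rose, 1 fell and 9 did not pass (camera higher, adjusted p = 0.047, p = 0.36 with estimated correlation).

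Lists of hepatocyte metabolism stood lower. In the urea cycle and amino acid catabolism list 17 of 23 fell and 6 did not pass (camera adjusted p = 1.1e-08, p = 0.071 with estimated correlation), with the urea cycle genes Asl (-2.5 ± 0.33) and Ass1 (-2.30 ± 0.36) and the transsulfuration genes Cth (-2.73 ± 0.39) and Cbs (-2.23 ± 0.34). Among cytochrome P450 and drug metabolism genes, 14 of 22 fell and 8 did not pass (16 fell adjusted over the list alone, camera adjusted p = 8.7e-08, p = 0.19 with estimated correlation). Falls included Cyp4v3 (-1.77 ± 0.23) and Cyp2c55 (-2.32 ± 0.37). Of bile acid synthesis and transport genes, 9 of 19 fell and 10 did not pass (camera adjusted p = 4.5e-05, p = 0.13 with estimated correlation), with the hydroxylase gene Cyp7b1 at -3.62 ± 0.45. Among fatty acid oxidation genes, 11 of 21 fell and 10 did not pass (camera adjusted p = 4.0e-05, p = 0.22 with estimated correlation). Falls included Cpt2 (-1.41 ± 0.21). For gluconeogenesis and glycogen genes, 8 of 14 fell and 6 did not pass (camera adjusted p = 4.4e-04, p = 0.13 with estimated correlation), with glycogen synthase Gys2 at -2.16 ± 0.38. Lipogenesis genes were divided, as 2 of 22 rose, 10 fell and 10 did not pass (camera lower, adjusted p = 0.0065, p = 0.28 with estimated correlation); Pklr (-1.31 ± 0.22) and Gpam (-1.38 ± 0.32) fell and Pnpla3 (1.98 ± 0.44) rose. Among cholesterol synthesis genes, 6 of 18 fell and 12 did not pass (7 fell adjusted over the list alone, camera adjusted p = 0.0011, p = 0.36 with estimated correlation). Of the plasma proteins, 9 of 28 fell and 19 did not pass (camera adjusted p = 0.0017, p = 0.19 with estimated correlation).

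Further lists bore on hepatocyte identity. Among hepatocyte transcription factors, 6 of 18 fell and 12 did not pass (1 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.012, p = 0.21 with estimated correlation). Falls included Cebpa (-1.86 ± 0.35) and Rxra (-1.26 ± 0.24), although the list's median of -0.41 became 0.17 under median scaling. Among male-biased liver genes, which include Hsd3b5 and Elovl3, 8 of 15 fell and 7 did not pass (10 fell adjusted over the list alone, camera adjusted p = 1.7e-06, p = 0.15 with estimated correlation). Of female-biased liver genes, 2 of 15 rose, 2 fell and 11 did not pass (camera lower, adjusted p = 0.95), and their median of 0.35 and mean of -0.07 differed in sign. Among pericentral Wnt-responsive genes, 1 of 17 rose, 1 fell and 15 did not pass (camera lower, adjusted p = 0.63). Among NRF2 and glutathione genes 4 of 24 rose, 1 fell and 19 did not pass (1 rose adjusted over the list alone, camera higher, adjusted p = 0.59). Among unfolded protein response genes, 4 of 22 rose, 7 fell and 11 did not pass (5 rose and 7 fell adjusted over the list alone, camera lower, adjusted p = 0.21) and among oxidative phosphorylation genes 4 of 25 fell and 21 did not pass (camera adjusted p = 0.13). Among pancreatic acinar genes, 4 of 7 fell and 3 did not pass (camera adjusted p = 0.036, p = 0.19 with estimated correlation).

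Markers of other cell types moved apart in the Sav1 tumours. Among macrophage and Kupffer cell markers, 15 of 24 rose, 4 fell and 5 did not pass (17 rose and 4 fell adjusted over the list alone, camera higher, adjusted p = 0.0017, p = 0.39 with estimated correlation): the pan-macrophage genes Mpeg1 (3.17 ± 0.34) and Lyz2 (3.36 ± 0.62) rose while the scavenger receptor gene Cd163 (-2.08 ± 0.39) of resident macrophages fell. Among inflammatory cytokine and NF-kB genes, 13 of 23 rose and 10 did not pass (14 rose adjusted over the list alone, camera adjusted p = 6.4e-06, p = 0.27 with estimated correlation). Rises included Tnfrsf12a (3.62 ± 0.40) and Nfkb2 (1.31 ± 0.23). Of the extracellular matrix and stellate cell genes, 15 of 34 rose, 2 fell and 17 did not pass (19 rose and 3 fell adjusted over the list alone, camera higher, adjusted p = 7.5e-04, p = 0.42 with estimated correlation); Lgals1 (3.44 ± 0.57) and Col4a1 (2.18 ± 0.41) rose and the stellate cell gene Lrat (-1.77 ± 0.35) fell. Among T cell and NK cell markers, 6 of 16 rose, 1 fell and 9 did not pass (12 rose and 1 fell adjusted over the list alone, camera higher, adjusted p = 0.023, p = 0.36 with estimated correlation), among B cell and plasma cell markers 4 of 12 rose and 8 did not pass (camera adjusted p = 0.098). Among neutrophil markers 3 of 14 rose and 11 did not pass (camera adjusted p = 0.014, p = 0.42 with estimated correlation). Among endothelial cell markers, 3 of 25 rose, 8 fell and 14 did not pass (camera lower, adjusted p = 0.089). Among interferon response genes, 6 of 22 rose, 1 fell and 15 did not pass (8 rose and 1 fell adjusted over the list alone, camera higher, adjusted p = 0.030, p = 0.44 with estimated correlation). Rises included Ifit2 (2.67 ± 0.42) and Usp18 (1.93 ± 0.48). Among acute phase genes 6 of 21 rose, 2 fell and 13 did not pass (camera higher, adjusted p = 0.52). Among erythrocyte genes, 1 of 10 rose, 2 fell and 7 did not pass (camera lower, adjusted p = 0.71), with a median of 0.32 and a mean of -0.16. The 3 lists left, the targeted genes, adipocyte markers and sex chromosome genes, held 2, 4 and 4 measured genes and were too small to test.

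With the array set as a block, 2774 genes changed between Sav1 tumour and floxed liver, and 948 did within set A (3 arrays against 3). Without Sav1 floxed liver 2 the count was 2930. Of the 24 lists called, 23 and 22 were also called in the same direction with the block and within set A, where the median of the cell cycle genes was 1.13 and that of the urea cycle list -1.70.

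**Figure D2:**
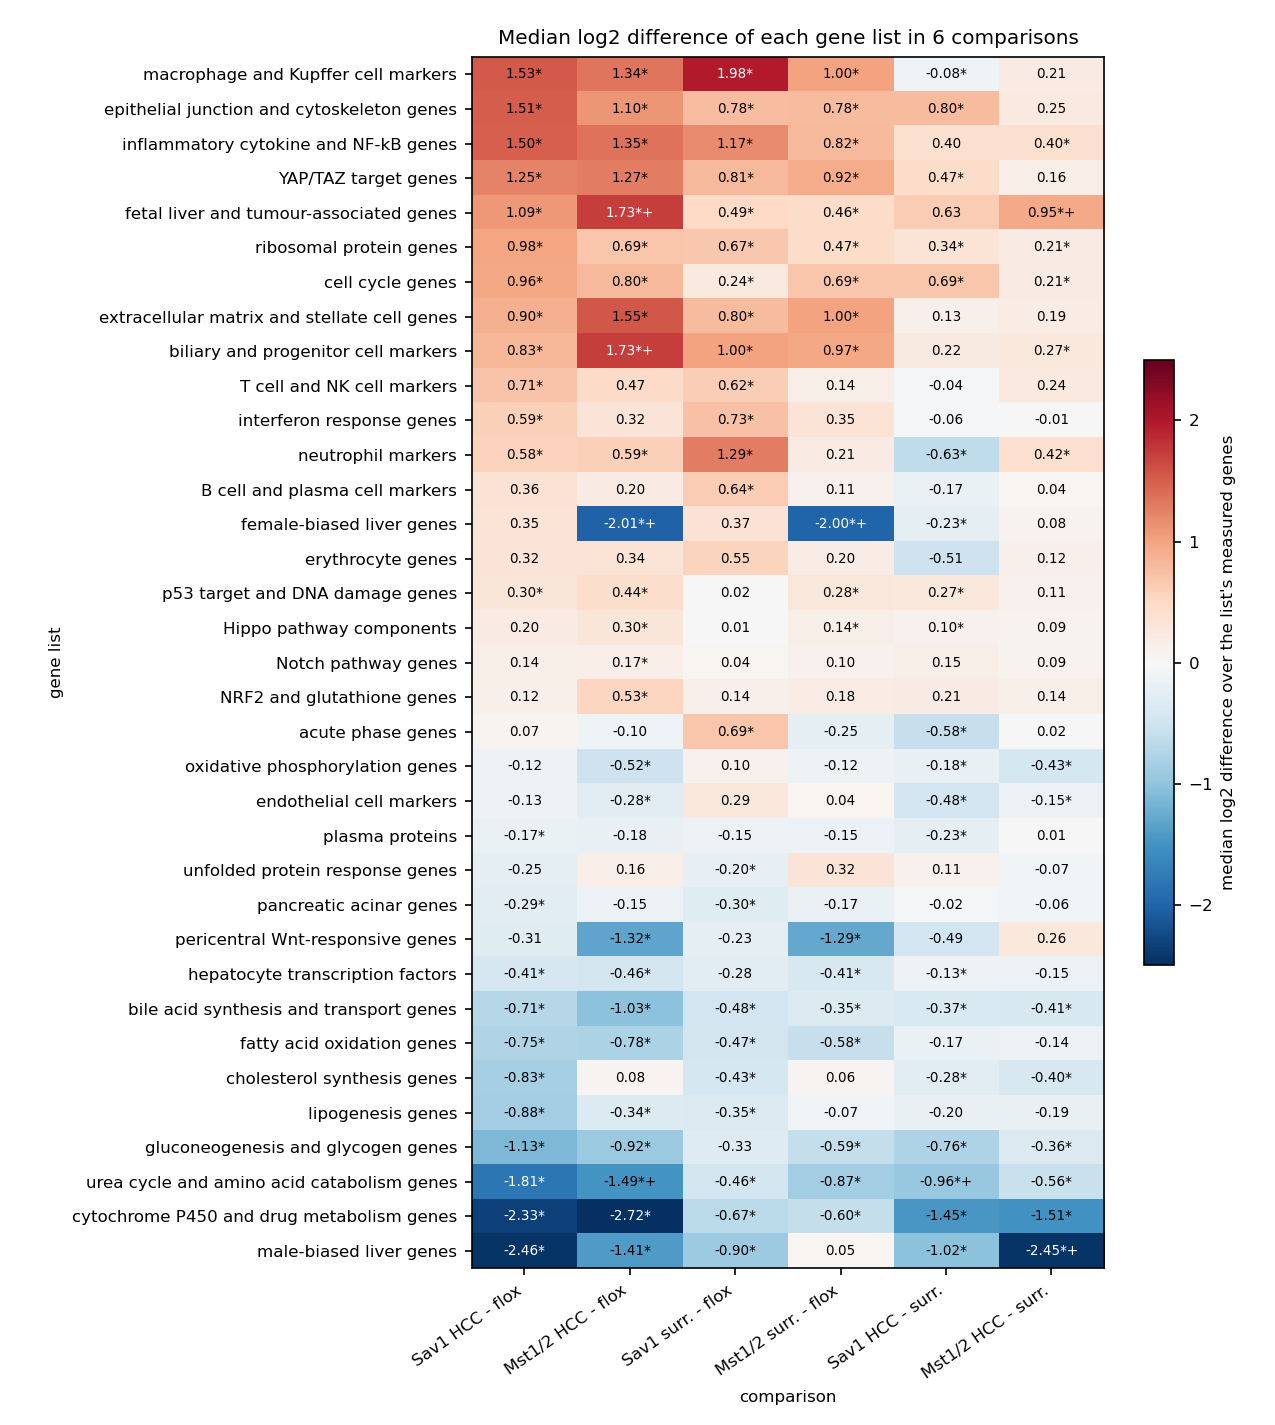
Median log2 difference over the measured genes of each of 35 gene lists (y axis) in 6 comparisons (x axis), as numbers and colour; a star marks a list called by camera with a preset correlation and a plus one called with an estimated correlation. The cell cycle genes have a median of 0.96 in Sav1 tumours against floxed liver and the cytochrome P450 genes one of -2.33; surr. stands for surrounding liver.

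In Mst1/2 tumours (n = 4) against Mst1/2 floxed livers (n = 3), Spink1 rose 298-fold (log2 difference 8.22 ± 1.14, adjusted p = 1.4e-05) and Igf2, the fetal insulin-like growth factor, rose 192-fold (log2 difference 7.59 ± 1.61, adjusted p = 0.0014). Gpc3 rose 115-fold (log2 difference 6.85 ± 0.63, adjusted p = 1.8e-08), and Psca, a surface antigen gene of epithelia, rose 124-fold (log2 difference 6.95 ± 0.91, adjusted p = 6.2e-06). Cyp2b13 and Cyp2b9, P450 genes of female mouse liver, fell 100.1-fold (log2 difference -6.64 ± 0.56, adjusted p = 4.5e-09) and 84.6-fold (log2 difference -6.40 ± 0.91, adjusted p = 1.9e-05), and the controls of this comparison carried the female pattern. In all, 2833 genes changed, 1578 higher and 1255 lower, with at least 2-fold changes in 973 and 578.

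Among other rises in the Mst1/2 tumours were those of Sftpd (6.12 ± 0.91), Cib3 (5.49 ± 1.14), Tspan8 (5.37 ± 0.86) and Chrnb1 (5.32 ± 0.55). Tff3 (at least 36.8-fold), Fgfbp1 (at least 27.8-fold) and Prr15l (at least 17.0-fold) were higher and above background in no floxed liver, as was Eif2s3y (at least 22.7-fold). Falls included Sult2a8 (-6.50 ± 1.15), Cyp4a14 (-6.46 ± 1.30), Cyp2b10 (-5.79 ± 0.66), Cyp2c29 (-5.70 ± 1.09), Ces1f (-5.69 ± 1.16) and Cyp2b23 (-5.42 ± 0.42), which encode enzymes of xenobiotic, lipid and bile acid metabolism. Xist (at least 22.3-fold), A1bg (at least 13.8-fold), Sult5a1 (at least 9.77-fold) and Rfx4 (at least 4.02-fold) were lower and above background in no tumour. For Eif2s3y, Prr15l and Rfx4 this holds for the tested probe, since another probe of the gene exceeded background there. All 49 changed genes named lay on the stated side of the floxed mean in 4 of 4 arrays.

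Among biliary and progenitor cell markers, 12 of 20 rose and 8 did not pass (18 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.6e-09, p = 0.033 with estimated correlation). Rises included Sox4 (3.76 ± 0.47) and Cldn6 (5.04 ± 0.69). Among fetal liver genes 10 of 17 rose and 7 did not pass (12 rose adjusted over the list alone, camera adjusted p = 1.9e-07, p = 0.033 with estimated correlation), with alpha-fetoprotein Afp at 4.2 ± 0.79. Among YAP/TAZ target genes, 12 of 19 rose, 1 fell and 6 did not pass (camera higher, adjusted p = 2.9e-05, p = 0.061 with estimated correlation). Rises included Ccn2 (3.37 ± 0.51) and Ankrd1 (4.94 ± 0.89). Of Hippo pathway components, 8 of 23 rose and 15 did not pass (camera adjusted p = 0.0014, p = 0.061 with estimated correlation), with the YAP-binding factors Tead2 (1.68 ± 0.31) and Tead4 (at least 1.88-fold) and the scaffold gene Wwc1 (1.88 ± 0.37). Of the cell cycle genes, 20 of 34 rose and 14 did not pass (25 rose adjusted over the list alone, camera adjusted p = 1.5e-09, p = 0.18 with estimated correlation). Rises included Prc1 (2.75 ± 0.58) and Mcm4 (1.41 ± 0.31). Among epithelial junction and cytoskeleton genes, 14 of 30 rose and 16 did not pass (17 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.7e-07, p = 0.074 with estimated correlation). Rises included Anxa5 (3.25 ± 0.40) and Krt8 (2.33 ± 0.30). Among extracellular matrix list, 16 of 34 rose, 1 fell and 17 did not pass (20 rose and 3 fell adjusted over the list alone, camera higher, adjusted p = 1.1e-06, p = 0.28 with estimated correlation). Rises included Sparc (3.42 ± 0.59) and Col1a1 (at least 3.36-fold). Macrophage and Kupffer cell markers again divided, as 9 of 24 rose, 2 fell and 13 did not pass (camera higher, adjusted p = 0.0041, p = 0.39 with estimated correlation). Rises included Mpeg1 (2.21 ± 0.40) and Cx3cr1 (3.22 ± 0.78) against Cd163 (-2.38 ± 0.46).

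Of the urea cycle and amino acid catabolism genes, 13 of 23 fell and 10 did not pass (18 fell adjusted over the list alone, camera adjusted p = 1.7e-09, p = 0.026 with estimated correlation). Falls included Cth (-2.62 ± 0.45) and Gnmt (-2.33 ± 0.41). Among cytochrome P450 and drug metabolism genes, 16 of 22 fell and 6 did not pass (20 fell adjusted over the list alone, camera adjusted p = 4.0e-10, p = 0.074 with estimated correlation). Among fatty acid oxidation genes, 10 of 21 fell and 11 did not pass (14 fell adjusted over the list alone, camera adjusted p = 7.3e-06, p = 0.20 with estimated correlation). Falls included Cpt2 (-1.49 ± 0.25) and Ehhadh (-2.06 ± 0.39). Among endothelial cell markers, 2 of 25 rose, 7 fell and 16 did not pass (2 rose and 8 fell adjusted over the list alone, camera lower, adjusted p = 0.039, p = 0.44 with estimated correlation). Falls included Oit3 (-2.60 ± 0.54) and Wnt2 (-1.77 ± 0.38), and their median of -0.28 became 0.03 under median scaling. Female-biased liver genes had a median of -2.01, as 8 of 15 fell and 7 did not pass (9 fell adjusted over the list alone, camera adjusted p = 1.9e-07, p = 0.0071 with estimated correlation); against the wild-type livers, which lack the Xist signal, the median was 0.21. Male-biased liver genes had a median of -1.41, as 5 of 15 fell and 10 did not pass (7 fell adjusted over the list alone, camera adjusted p = 2.2e-04, p = 0.21 with estimated correlation). Falls included Mup20 (-4.78 ± 0.94) and Cyp2d9 (-2.75 ± 0.87), and a median of -4.43 against the wild-type livers. The Mup genes are near-identical paralogs, so which of them changed is uncertain. Of 35 lists 26 were called, and 4 with an estimated correlation.

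Against the 2 wild-type livers instead of the floxed livers, 2975 genes changed in the Mst1/2 tumours, and 20 of the 26 lists called were called in the same direction. Of the 49 named genes 41 passed; Cyp4a14 (-0.69), Rfx4 (-0.23), Cth (-0.70), Cyp2b13, Cyp2b9, A1bg, Xist and Cd163 did not. Without Mst1/2 floxed liver 4, 5 or 6 the count was 1817, 1839 or 1821.

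**Figure D3:**
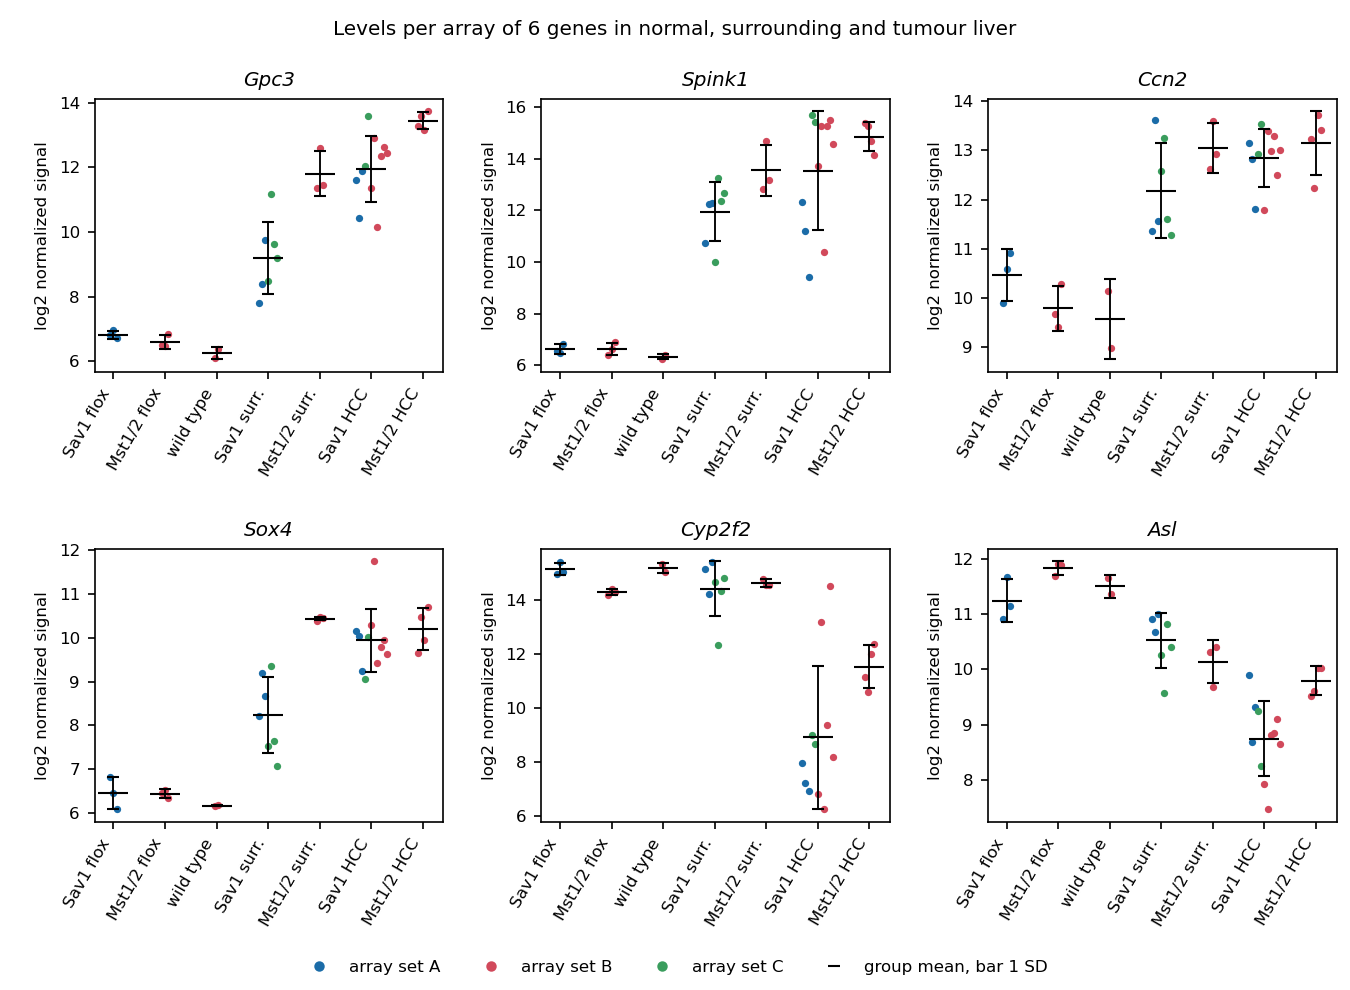
Log2 normalized signal (y axis) of Gpc3, Spink1, Ccn2, Sox4, Cyp2f2 and Asl on each of the 33 arrays by group (x axis); points are arrays coloured by array set, and bars show the group mean ± 1 SD. Gpc3 averages 6.83 in Sav1 floxed livers, 9.21 in Sav1 surrounding livers and 11.95 in Sav1 tumours, and Cyp2f2 spreads from 6.24 to 14.53 among the Sav1 tumours.

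In surrounding liver of Sav1 knockout mice (n = 7) against Sav1 floxed liver (n = 3), Lcn2 rose 38.6-fold (log2 difference 5.27 ± 0.69, adjusted p = 2.3e-05), H2-Aa 30.4-fold (log2 difference 4.92 ± 0.63, adjusted p = 2.1e-05), and the calprotectin genes S100a8 and S100a9 rose 17.0-fold and 13.8-fold. The metal-binding Mt1 (3.94 ± 0.78), the interferon-responsive Ifi27l2a (3.82 ± 0.57) and the chemokine gene Ccl5 (3.37 ± 0.77) also rose. Hsd3b5 fell 70.0-fold (log2 difference -6.13 ± 0.83, adjusted p = 3.8e-05), with falls of Elovl3 (-4.07 ± 0.40), Car3 (-3.35 ± 0.78), Camk2b (-3.20 ± 0.58), Cyp2b10 (-2.94 ± 0.60), Hectd2os (-2.71 ± 0.35), Cyp7b1 (-2.70 ± 0.47) and Alas2 (-2.45 ± 0.69). In all, 1463 genes changed, 702 higher and 761 lower, with at least 2-fold changes in 424 and 150.

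Among macrophage and Kupffer cell markers in the Sav1 surrounding liver, 14 of 24 rose and 10 did not pass (19 rose adjusted over the list alone, camera adjusted p = 6.1e-12, p = 0.23 with estimated correlation), and here Cd163 (2.29 ± 0.41), Mpeg1 (2.74 ± 0.36) and Lyz2 (3.12 ± 0.66) all rose. Among neutrophil markers, 9 of 14 rose and 5 did not pass (10 rose adjusted over the list alone, camera adjusted p = 6.9e-09, p = 0.23 with estimated correlation), including the granule enzyme gene Mpo at 2.11 ± 0.34. Among T cell and NK cell markers, 7 of 16 rose and 9 did not pass (9 rose adjusted over the list alone, camera adjusted p = 1.6e-04, p = 0.23 with estimated correlation). Among inflammatory cytokine and NF-kB genes, 8 of 23 rose and 15 did not pass (10 rose adjusted over the list alone, camera adjusted p = 1.8e-06, p = 0.26 with estimated correlation). Rises included Vcam1 (2.29 ± 0.48) and Birc3 (at least 1.47-fold). Among acute phase genes, 5 of 21 rose and 16 did not pass (8 rose adjusted over the list alone, camera adjusted p = 1.8e-04, p = 0.23 with estimated correlation). Rises included Fgl1 (1.73 ± 0.32) and Socs3 (2.22 ± 0.44). Among interferon response genes 5 of 22 rose and 17 did not pass (8 rose adjusted over the list alone, camera adjusted p = 1.6e-04, p = 0.25 with estimated correlation). Rises included Irf7 (1.65 ± 0.31) and Ifit2 (1.94 ± 0.45). Among YAP/TAZ target genes, 3 of 19 rose and 16 did not pass (4 rose adjusted over the list alone, camera adjusted p = 5.6e-04, p = 0.23 with estimated correlation). Rises included Axl (1.71 ± 0.35) and Ccn2 (1.71 ± 0.46).

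Higher in the Sav1 surrounding liver and above background in no floxed liver were Spink1 (at least 36.6-fold), Cib3 (at least 14.1-fold), Prtn3 (at least 7.62-fold) and Esm1 (at least 5.65-fold). All 31 changed genes named lay on the stated side of the floxed mean in 7 of 7 arrays. With the array set as a block 558 genes changed, and 21 did within set A (3 arrays against 3); 19 and 20 of the 23 lists called were called in the same direction in those fits. Without Sav1 floxed liver 2 or 3 the count was 307 or 756.

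In surrounding liver of Mst1/2 knockout mice (n = 3) against Mst1/2 floxed liver (n = 3), Gpc3 rose 36.8-fold (log2 difference 5.20 ± 0.67, adjusted p = 1.4e-05), Spink1 rose 121-fold and Cib3 112-fold. Rises of Hamp2 (6.80 ± 1.5), Sftpd (4.98 ± 0.97), Spon2 (4.43 ± 0.61), Nat8 (4.34 ± 0.56) and Espn (4.16 ± 0.75) accompanied them; Hamp2 belongs to the hepcidin family of iron regulators. Cyp2b9 fell 106-fold (log2 difference -6.72 ± 0.98, adjusted p = 7.2e-05). Falls included Sult2a2 (-6.57 ± 1.07), Cyp4a14 (-5.93 ± 1.39), Cyp2b23 (-5.34 ± 0.45), Cyp2b10 (-4.89 ± 0.71), Cyp17a1 (-4.70 ± 0.59), Mmd2 (-4.27 ± 0.53) and Igfbp2 (-3.77 ± 1.03). Higher and above background in no floxed liver were Eif2s3y (at least 28.3-fold), Ang4 (at least 11.3-fold), Prr15l (at least 11.2-fold) and Esm1 (at least 8.19-fold); lower and above background in no surrounding liver were Cyp2b13 (at least 87.8-fold), Xist (at least 22.2-fold), Nlrp12 (at least 17.9-fold) and Sult3a2 (at least 6.79-fold). In all, 543 genes changed, 358 higher and 185 lower, with at least 2-fold changes in 283 and 106.

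Among epithelial junction and cytoskeleton genes, 10 of 30 rose, 1 fell and 19 did not pass (14 rose and 1 fell adjusted over the list alone, camera higher, adjusted p = 1.6e-09, p = 0.061 with estimated correlation) in the Mst1/2 surrounding liver, with Anxa5 (3.07 ± 0.43) and S100a11 (4.01 ± 0.58). Among biliary and progenitor cell markers, 4 of 20 rose and 16 did not pass (11 rose adjusted over the list alone, camera adjusted p = 4.5e-09, p = 0.061 with estimated correlation). Rises included Sox4 (4.00 ± 0.50) and Elf3 (3.06 ± 0.57). Among YAP/TAZ target genes, 4 of 19 rose and 15 did not pass (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.1e-05, p = 0.080 with estimated correlation). Rises included Ccn2 (3.26 ± 0.54) and Crim1 (1.51 ± 0.36). Among cell cycle genes, 3 of 34 rose and 31 did not pass (12 rose adjusted over the list alone, camera adjusted p = 4.5e-09, p = 0.25 with estimated correlation). Rises included Cdc20 (2.06 ± 0.53) and Stmn1 (2.27 ± 0.58). Female-biased liver genes had a median of -2.0, as 8 of 15 fell and 7 did not pass (camera adjusted p = 1.2e-13, p = 6.1e-05 with estimated correlation), and a median of 0.15 against the wild-type livers. Among urea cycle and amino acid catabolism genes, 2 of 23 fell and 21 did not pass (4 fell adjusted over the list alone, camera adjusted p = 1.1e-05, p = 0.10 with estimated correlation). Falls included Asl (-1.70 ± 0.41) and Prodh2 (-1.88 ± 0.47). All 34 changed genes named lay on the stated side of the floxed mean in 3 of 3 arrays. Of the 19 lists called, 1 was called with an estimated correlation.

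Against the wild-type livers 1231 genes changed in the Mst1/2 surrounding liver, and 12 of the 19 lists were called in the same direction, the urea cycle list not among them. Of the 34 named genes 22 passed in the same direction. Cyp17a1 stood at 1.04 and Sult2a2 at 0.20, above the control, and Cyp4a14 (-0.17), Cyp2b13 (-0.80), Cyp2b9, Cyp2b10, Sult3a2, Hamp2, Igfbp2, Xist, Asl and Prodh2 did not pass. The count was 230, 287 or 251 without Mst1/2 floxed liver 4, 5 or 6 and 357, 184 or 286 without surrounding liver 1, 2 or 3.

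Within the Sav1 line, the largest falls in tumours (n = 11) against surrounding liver (n = 7) included some genes of resident macrophages and sinusoidal endothelium. Fcna, Cd163, Vsig4 and Clec4f, genes of Kupffer cells, fell 21.6-fold, 20.7-fold, 19.3-fold and 17.6-fold, and the sinusoidal lectin gene Clec4g fell 13.6-fold (log2 difference -3.77 ± 0.67, adjusted p = 3.1e-04). Nnmt (-4.13 ± 0.51), Lrtm1 (-3.28 ± 0.33) and Nlrp12 (-3.22 ± 0.31) fell too. Rises were led by Espn (2.88 ± 0.44), Parm1 (2.25 ± 0.23), Adam32 (2.16 ± 0.34), Osbpl3 (2.0 ± 0.25), Anxa2 (1.97 ± 0.27), Pls1 (1.93 ± 0.22), Tlcd5 (1.88 ± 0.22) and Slc23a3 (1.78 ± 0.44); Pls1, like Espn, bundles actin. In all, 1798 genes changed, 983 higher and 815 lower, with at least 2-fold changes in 229 and 296.

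Among cell cycle genes, 18 of 34 rose and 16 did not pass (25 rose adjusted over the list alone, camera adjusted p = 1.9e-12, p = 0.15 with estimated correlation) in Sav1 tumours against surrounding liver, with Mcm7 (0.83 ± 0.15) and Nusap1 (1.48 ± 0.29). In the urea cycle and amino acid catabolism list 15 of 23 fell and 8 did not pass (18 fell adjusted over the list alone, camera adjusted p = 4.3e-15, p = 0.0034 with estimated correlation). Falls included Cth (-2.21 ± 0.29) and Asl (-1.78 ± 0.24). Among cytochrome P450 genes, 11 of 22 fell and 11 did not pass (14 fell adjusted over the list alone, camera adjusted p = 5.2e-10, p = 0.15 with estimated correlation). Falls included Cyp2f2 (-5.50 ± 0.80). Among endothelial cell markers, 2 of 25 rose, 11 fell and 12 did not pass (3 rose and 11 fell adjusted over the list alone, camera lower, adjusted p = 3.3e-06, p = 0.15 with estimated correlation), with the sinusoidal genes Wnt2 (-1.75 ± 0.24), Dnase1l3 (-2.20 ± 0.34) and Stab2 (-1.95 ± 0.31). Among macrophage and Kupffer cell markers, 2 of 24 rose, 5 fell and 17 did not pass (2 rose and 6 fell adjusted over the list alone, camera lower, adjusted p = 0.0048, p = 0.48 with estimated correlation). Falls included Timd4 (-2.73 ± 0.27). Among neutrophil markers, 4 of 14 fell and 10 did not pass (6 fell adjusted over the list alone, camera adjusted p = 7.8e-05, p = 0.22 with estimated correlation). Falls included Mpo (-1.59 ± 0.24). Among acute phase genes 2 of 21 rose, 7 fell and 12 did not pass (2 rose and 10 fell adjusted over the list alone, camera lower, adjusted p = 1.3e-04, p = 0.15 with estimated correlation). Falls included Orm1 (-3.09 ± 0.55). Among Hippo pathway components, 7 of 23 rose and 16 did not pass (8 rose adjusted over the list alone, camera adjusted p = 0.011, p = 0.15 with estimated correlation). Rises included Amotl2 (0.85 ± 0.10) and Tead4 (1.0 ± 0.16). Among YAP/TAZ target genes 6 of 19 rose, 1 fell and 12 did not pass (camera higher, adjusted p = 0.010, p = 0.22 with estimated correlation). Eif2s3y was lower in the tumours by -1.76 ± 0.45 (adjusted p = 0.0090).

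Of the 31 changed genes named, 27 lay on the stated side of the surrounding liver mean in all 11 arrays, and the others in at least 9. Esrrb was at least 1.64-fold lower by a probe above background in no tumour, though another of its probes was. With the array set as a block 1430 genes changed, while 50 changed within set A (3 tumours against 3 surrounding livers) and 803 within set C (2 against 4), and 18 and 17 of the 20 lists called were called in the same direction with the block and within set A. With an estimated correlation 1 list was called, the urea cycle list.

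**Figure D4:**
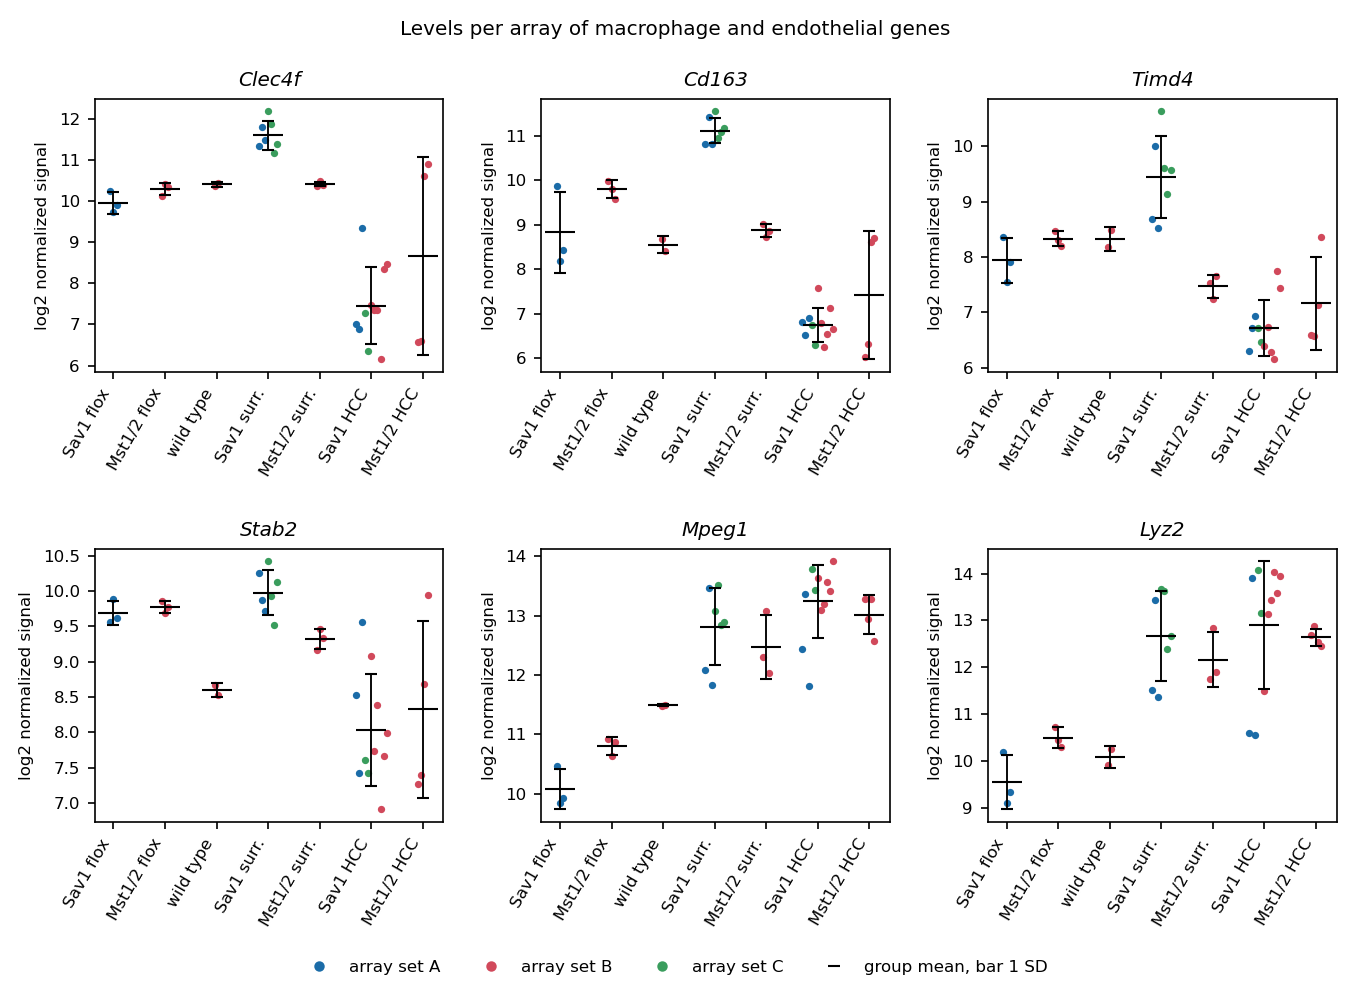
Log2 normalized signal (y axis) of the Kupffer cell genes Clec4f, Cd163 and Timd4, the sinusoidal endothelial gene Stab2 and the pan-macrophage genes Mpeg1 and Lyz2 on each of the 33 arrays by group (x axis); points are arrays coloured by array set, and bars show the group mean ± 1 SD. Cd163 averages 11.12 in Sav1 surrounding livers and 6.75 in Sav1 tumours, whereas Mpeg1 averages 12.82 and 13.24.

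Within the Mst1/2 line, tumours (n = 4) differed from surrounding liver (n = 3) in 9 genes, 3 higher and 6 lower, at the threshold used, and 1111 genes had an unadjusted p under 0.05. The major urinary protein genes Mup5, Mup20, Mup6 and Mup21, near-identical paralogs expressed in male liver, fell: Mup5 (-5.33 ± 0.93), Mup20 (-5.04 ± 0.94), Mup6 (-5.00 ± 0.83) and Mup21 (-4.98 ± 1.01). Slc23a3, of the vitamin C transporter family, rose 14-fold (log2 difference 3.80 ± 0.70, adjusted p = 0.018) and Pros1, encoding protein S of the coagulation system, rose 2.09-fold (log2 difference 1.06 ± 0.21, adjusted p = 0.047). Scnn1b, a sodium channel subunit gene, was at least 1.16-fold higher and Hectd2os 5.42-fold lower. All 8 changed genes named lay on the stated side of the surrounding liver mean in 4 of 4 arrays.

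Several lists moved together in the Mst1/2 tumours against their surrounding liver although few or no members passed singly. Male-biased liver genes had a median of -2.45: 1 of 15 fell and 14 did not pass (10 fell adjusted over the list alone, camera adjusted p = 7.5e-14, p = 0.021 with estimated correlation). Fetal liver and tumour-associated genes had a median of 0.95: 17 did not pass (8 rose adjusted over the list alone, camera adjusted p = 1.9e-09, p = 0.021 with estimated correlation). Cytochrome P450 and drug metabolism genes had a median of -1.51: 22 did not pass (10 fell adjusted over the list alone, camera adjusted p = 4.1e-12, p = 0.081 with estimated correlation). The urea cycle list had a median of -0.56: 23 did not pass (1 fell adjusted over the list alone, camera adjusted p = 2.1e-07, p = 0.055 with estimated correlation). At an unadjusted p under 0.05, 10, 10 and 8 genes of the male-biased, P450 and urea cycle lists were lower and 9 of the fetal list higher. Of 35 lists 14 were called, and 2 with an estimated correlation. The count of 9 genes was 1 without surrounding liver 1 or 3, and 2, 2, 49 or 88 without tumour 1, 2, 3 or 4.

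Between the tumours of the 2 knockouts, 538 genes differed, 200 higher in Sav1 tumours (n = 11) and 338 higher in Mst1/2 tumours (n = 4). Igf2 was 48.0-fold (log2 difference -5.59 ± 1.24, adjusted p = 0.0097) lower in Sav1 than in Mst1/2 tumours, and the claudin gene Cldn6 20.7-fold (log2 difference -4.37 ± 0.53, adjusted p = 3.0e-05) lower, with Psca (-3.38 ± 0.69), Cyp2a12 (-2.83 ± 0.80) and Peg3 (-2.79 ± 0.80). Mup20 was 16-fold (log2 difference 3.99 ± 0.72, adjusted p = 0.0017) higher in Sav1 tumours, with Mup5 (3.54 ± 0.71), Cyp4a12a (3.37 ± 0.93), Mup6 (3.19 ± 0.63) and Mup21 (3.05 ± 0.77). Biliary and progenitor cell markers were lower in Sav1 tumours (5 of 20 genes lower, 5 lower adjusted over the list alone, camera adjusted p = 1.2e-04, p = 0.49 with estimated correlation), as were fetal liver genes (5 of 17 genes lower, 1 higher and 9 lower adjusted over the list alone, camera adjusted p = 1.2e-04, p = 0.49 with estimated correlation). The extracellular matrix list (3 of 34 genes lower, 1 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0012, p = 0.88 with estimated correlation) and the urea cycle list (2 of 23 genes lower, 1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.016, p = 0.76 with estimated correlation) were also lower, and male-biased liver genes were higher (3 of 15 genes higher, 5 higher adjusted over the list alone, camera adjusted p = 1.1e-04, p = 0.49 with estimated correlation). Within set B, which holds 6 of the Sav1 tumours and all 4 Mst1/2 tumours, 1705 genes differed, although Igf2 (-4.53), Cyp2a12 and Peg3 did not pass there, and 1923 did with the array set as a block, where 3 of the 6 lists called were called again. Without Mst1/2 tumour 1, 2 or 4 the count was 167, 168 or 295.

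Between the surrounding livers, 133 genes differed, 67 higher in Sav1 (n = 7) and 66 higher in Mst1/2 samples (n = 3). Higher in the Sav1 surrounding liver were Igfbp2 (3.57 ± 0.87), Apoa4 (3.46 ± 0.74), Apoc2 (3.24 ± 0.75), Noct (2.89 ± 0.66) and Cd163 (2.24 ± 0.41), where Apoa4 and Apoc2 encode apolipoproteins. Lower were Ptgds (-3.31 ± 0.73), Spon2 (-2.92 ± 0.51), Tsc22d1 (-2.65 ± 0.43), Gpc3 (-2.60 ± 0.57) and Sox4 (-2.21 ± 0.42). Neutrophil markers were higher in the Sav1 samples (2 of 14 genes higher, 8 higher adjusted over the list alone, camera adjusted p = 3.5e-11, p = 0.28 with estimated correlation), with Mpo (1.96 ± 0.34) and Elane (at least 1.47-fold), as were macrophage and Kupffer cell markers (2 of 24 genes higher, 3 higher adjusted over the list alone, camera adjusted p = 4.0e-06, p = 0.59 with estimated correlation), with Timd4 (1.98 ± 0.38). Epithelial junction and cytoskeleton genes were lower (3 of 30 genes lower, 1 higher and 10 lower adjusted over the list alone, camera adjusted p = 3.1e-06, p = 0.37 with estimated correlation), with Anxa5 (-1.64 ± 0.36), Tubb2b (-2.08 ± 0.49) and Cldn1 (-1.58 ± 0.39). With the replicate number as a block, over samples 1 to 3 of each line, 849 genes differed, Timd4 and Cldn1 not among them, and 16 lists were called against 11. The Sav1 surrounding livers lay in sets A and C and the Mst1/2 ones in set B, so array set and group cannot be told apart between these samples alone; a block estimated over all groups gave 743 genes, without Igfbp2, Apoc2 and Sox4, and 5 lists. The count was 78 or 73 without Sav1 surrounding liver 4 or 7, and 29, 21 or 22 without Mst1/2 surrounding liver 1, 2 or 3.

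Both tumour types shared 1698 genes changed in the same direction against their own floxed livers, 959 higher and 739 lower, where independent lists of those sizes would share 274 and 199, and 37 genes changed in opposite directions. Across genes, which are not independent replicates, the log2 differences of the 2 comparisons had a Pearson r of 0.735 and a Spearman rho of 0.599. Ccn2, Gpc3, Spink1 and Sox4 were among the shared rises, and Cth, Asl, Cpt2 and Sult2a8 among the shared falls. Against Sav1 floxed livers, 1266 genes changed in the same direction in tumour and surrounding liver, 559 higher and 707 lower, against 122 and 121 for independent lists. Against Mst1/2 floxed livers, 502 did, 336 higher and 166 lower, against 40.4 and 16.6. These 2 pairs of comparisons share their controls: 50 simulations of unchanged groups against the same controls gave an r of 0.742 where 0.828 was observed in the Sav1 line, and 0.535 where 0.854 was observed in the Mst1/2 line. The covariance was 0.367 against a simulated 0.058 in the Sav1 line and 0.418 against 0.058 in the Mst1/2 line. The simulations gave 0 shared calls with limma. With 3 controls per line a split into parts of at least 2 was not possible, so part of the excess may come from the shared controls. The surrounding livers of the 2 lines shared 177 genes in the same direction, 125 higher and 52 lower, against 18 and 10.1, with 10 in opposite directions.

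The difference between the lines in the change from floxed liver to tumour passed for 154 genes, 87 with the larger value in the Sav1 line and 67 in the Mst1/2 line. It was largest for Cyp17a1 (4.93 ± 0.73) and Saa2 (3.49 ± 0.77) and, in the other direction, for Gpc1 (-3.08 ± 0.62) and Spon2 (-3.08 ± 0.75). From floxed to surrounding liver, 84 genes passed, led by Cyp17a1 (6.78 ± 0.78) and Cyp2b9 (5.78 ± 1.28) and Hsd3b5 (-5.83 ± 1.28) and Spon2 (-4.99 ± 0.80). From surrounding liver to tumour, 12 passed, among them Espn (4.67 ± 0.83) and Amotl2 (1.0 ± 0.19) and Cd163 (-2.92 ± 0.54) and Timd4 (-2.42 ± 0.49). Cyp17a1 and Cyp2b9 are female-biased and Hsd3b5 male-biased in mouse liver, and the controls of the lines differed in their sex pattern. With wild-type livers as the Mst1/2 control, 123 and 60 genes passed in the first 2 of these tests, but only 0 and 1 of the 10 genes that the naming rule had taken in each, the latter Spon2. Cyp17a1 (-0.81) and H2-T10 (-0.85) turned in the first and Lcn2 (-0.09) in the second, where Hsd3b5 was at 0.00. With the array set as a block 51, 61 and 12 genes passed, among them 4 of 10, 5 of 10 and 5 of 7 taken by the rule.

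Among the normal livers, 726 genes differed between the 3 groups by limma's F test. Between Sav1 and Mst1/2 floxed livers 479 genes differed, 176 higher and 303 lower in Sav1. Hsd3b5 (5.93 ± 0.98), Mup21 (3.90 ± 1.08), Nat8 (3.86 ± 0.56), Elovl3 (3.56 ± 0.47) and Cyp7b1 (3.19 ± 0.56) were higher in the Sav1 floxed livers, and Cyp17a1 (-4.88 ± 0.59), Cyp2b13 (-4.57 ± 0.60), Saa1 (-4.39 ± 1.16), Cyp2b9 (-3.87 ± 0.98) and A1bg (-3.70 ± 0.69) lower. These groups lay in different array sets and carried different sex patterns, so line, array set and sex cannot be told apart between them. The count was 230 or 236 without Sav1 floxed liver 2 or 3 and 238, 222 or 230 without Mst1/2 floxed liver 4, 5 or 6.

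Quantile normalization sets the arrays' distributions equal, so changes are relative to the bulk of genes. Under median scaling the median over all genes moved from 0.05 to 0.29 in Sav1 tumours against floxed liver, from 0.00 to 0.18 in the Mst1/2 tumours, from 0.02 to 0.21 in Sav1 surrounding liver and from 0.00 to 0.16 in Mst1/2 surrounding liver. The share of higher genes among those changed was then 87.4% against 52.2%, 82.5% against 55.7%, 92.3% against 48.0% and 89.1% against 65.9% in these 4 comparisons. It was 68.6% against 54.7% for Sav1 tumour against surrounding liver and 44.4% against 33.3% for Mst1/2 tumour against surrounding liver. No list called under both normalizations changed its direction.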

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

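The tests of the 3 patterns weighed here were chosen after the result was seen, except that of the 10 added cell markers together and the splits of the samples other than those that part numbered pairs or keep the floxed livers in place.

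Female-biased liver genes stood lower in Mst1/2 tumours than in Mst1/2 floxed livers, where 8 of them fell. Against the wild-type livers, which lack the floxed livers' Xist signal, the median of these 8 genes was -0.32. That of all 15 in Mst1/2 surrounding liver was 0.15. The wild-type livers had the 8 lower too, so loss of Mst1/2 stays open. A candidate explanation is that the floxed livers of this line came from female mice. Outside the sex lists 2817 genes changed, and 60.2% of them (1696) also passed against the wild-type livers in the same direction and 5 in the opposite one. In 50 simulations of tumours equal to the wild-type livers, shared tumour arrays gave at most 0.05%. The 1696 passed with controls low in Xist, which argues against Xist-positive ones as the cause of most. For other genes it stays open.

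Kupffer cell and sinusoidal endothelial markers were lower in Sav1 tumours than in surrounding liver: of 49 macrophage and endothelial markers 16 fell, with a median of -1.96, and 4 rose. The array set is argued against, since the 13 members that fell within set C alone had a median of -1.81 in set A. There the whole macrophage and endothelial lists had medians of -0.43 and -0.27 (0.13 and -0.67 in set C). A lower share of all non-hepatocytes stays open, as the matrix and stellate list had medians of 0.13 and, in set A, -0.15. Of 10 other markers that no fixed list holds, 9 fell, with a median of -1.03: it was -1.23 over 6 sinusoidal ones, among them Mrc1 (-1.99 ± 0.26) and F8 (-2.0 ± 0.20) while Flt4 (-0.08 ± 0.09) did not pass, and -0.61 over 4 of Kupffer cells, with Cd207 at -1.61 ± 0.48, Slc40a1 at -0.86 ± 0.16, Il18bp at -0.37 ± 0.09 and Kcna2 at -0.31 ± 0.09. Fewer sinusoidal cells in the tumours may account for their part of the pattern, while the 4 added Kupffer cell markers do not decide on fewer such cells, though Clec4f (-4.14), Cd163 (-4.37) and Timd4 (-2.74) of the fixed list fell further, and lower expression per cell stays open for both.

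Y-linked genes were lower in Sav1 tumours than in surrounding liver (Eif2s3y -1.76 ± 0.45, limma adjusted p = 0.0090; Kdm5d -0.73 ± 0.25, adjusted p = 0.0497). Female mice among them are argued against by the brightest Xist probe, ILMN_2475156, whose highest tumour level of 6.73 lay below the lowest of 11.22 in the Mst1/2 floxed livers, and a variant under the Eif2s3y probe by the relation of Eif2s3y to Kdm5d over the 11 tumours, 1 relation tested (Pearson r = 0.938, permutation p = 5e-05; Spearman rho = 0.882, permutation p = 6e-04; r = 0.869 over 9 tumours without the 2 farthest from the median and 0.903 over the 6 in set B). Within sets A and C, Eif2s3y differed between tumour and surrounding liver by -2.47 and -2.88 and Kdm5d by -1.0 and -1.34. Loss of the Y chromosome or of its expression in part of the tumour cells is a candidate explanation that was not tested.

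Chance was tested by splitting compared arrays anew. It is excluded against flox for Sav1 tumour (4650 genes; 1 of 100 splits as large, highest other 567), Mst1/2 tumour (2833; 1 of 35; 1270) and Sav1 surrounding liver (1463; 1 of 100; 697). For genes both tumours share (1698; 1 of 100; 12) splits with few calls cannot tell. For Sav1 tumour against surrounding liver (1798) it is excluded with 2 of 100 splits as large; the other split, with 2407 genes, set 7 tumours against the surrounding livers with tumours 1, 2, 3 and 10, which points to structure among the tumours; the count with the array set as a block was 1430. Chance is not excluded for Mst1/2 tumour against surrounding liver (9; 3 of 35; 83), the tumours of the lines (538; 5 of 100; 1255), the line difference in tumour against flox in splits that keep the floxed livers in place (154; 34 of 100; 1148) and, in splits that part the 3 numbered pairs of surrounding livers as the real one does, the line differences in surrounding liver against flox (84; 5 of 100; 514) and tumour against surrounding liver (12; 10 of 100; 208), where larger counts in other splits point to structure among the samples; without regard to pairs 4 and 5 of 100 were as large (highest other 225 and 193). With the floxed livers split too, 4 of 100 reached 154 (highest other 330), but the other 3 swapped the floxed livers of the lines whole. With 10 splits, those of Mst1/2 surrounding liver against flox (543; highest other 0 in limma, with up to 251 at an unadjusted p under 0.05, against 2383) and of the floxed livers (479; 1) are too few, as are the 8 that part all 3 pairs between the surrounding livers of the lines (133; 0, with up to 1697 at that p, against 1793; 84 over 100 splits without regard to pairs); 1 split of each, the real one, was as large. The counts of called lists were matched or passed by 8 of 100, 2 of 35, 6 of 100, 1 of 10 (too few), 7 of 100, 5 of 35, 65 of 100 and 2 of 8 (too few) splits in the 8 comparisons in the order of the report (real 24, 26, 23, 19, 20, 14, 6 and 11; highest other 28, 26, 27, 17, 25, 17, 24 and 11), so chance is not excluded for the number of lists in the other 6.

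Arrays far from their group were sought only in Sav1 surrounding liver and Mst1/2 tumours. They occurred for 12 of 161 pairs of named gene and group, against 8 by chance (1 in 20). Sav1 surrounding liver 4 had Cyp2b9 (12.27), Acot3 (11.49) and A1bg (8.29). Liver 5 had Mt1 (14.84), Cyp2f2 (12.32), Tlcd5 (8.52) and Hs3st3a1 (8.28), and liver 2 Ifit2 (11.27) and Nusap1 (8.67). Liver 1 had Cldn1 (11.29), liver 6 Hsd3b5 (11.66), and Mst1/2 tumour 3 Cyp2b9 (8.44).

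The lines differed by limma's interaction test, in Sav1 minus Mst1/2 on the log2 scale, in tumour against flox for Cyp17a1 (4.93), Saa2 (3.49), Abhd1 (3.3), H2-T10 (2.76), Mmd2 (2.69), Gpc1 (-3.08), Spon2 (-3.08), Nat8 (-3.07), Mme (-2.92) and Tsc22d1 (-2.82). In surrounding liver against flox they differed for Cyp17a1 (6.78), Cyp2b9 (5.78), Acot3 (4.55), Lcn2 (4.44), A1bg (4.05), Hsd3b5 (-5.83), Spon2 (-4.99), Elovl3 (-4.13), Nat8 (-4.06) and Tsc22d1 (-3.10), and in tumour against surrounding liver for Espn (4.67), Amotl2 (1.0), Cd163 (-2.92), Timd4 (-2.42), Ms4a8a (-2.18), Smc1b (-1.31) and Hs3st3a1 (-1.0). With the wild-type livers as Mst1/2 control 0 of the first 10 and 1 of the next 10, Spon2, passed. Of the 5008 unnamed probes above background, which no comparison of genes used, 1252, 618, 528, 78, 292, 2, 119 and 39 passed in the first 8 comparisons, 81, 9 and 2 in the line differences and 290 between the floxed livers.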

How the results depend on the processing

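The settings chosen only after the data were seen were the offset of 16, the array set as a block, the single array sets, the wild-type livers and the 5 normal livers with low Xist as Mst1/2 control, and, for the gene lists, median scaling and the replicate block. The cause of a moved value was not tested except where fewer samples or genes entered. Counts of changed genes stayed within 1.5 times in every comparison with the authors' processed values, no background correction, a normexp offset of 16, the 95th percentile of background in place of the 99th, no filter on dim probes, and trended robust moderation. A detection p filter was replaced by that percentile because no detection p was in the files, normexp with an offset of 50 equalled the setting used, and the slide as a block was not run because no slide was named. Low signal over background limits calls, as 12527 probes exceeded background on no array.

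Under median scaling, 333 genes differed between the tumours, 82 between the surrounding livers, 53 between the floxed livers and 204 among the normal livers, and 19 and 31 differed between the lines in tumour and in surrounding liver against flox. Requiring a probe above background on every array of a group left fewer genes tested and gave 15 genes for Mst1/2 tumour against surrounding liver and 19 for the line difference in that step; the mean of a gene's probes gave 17 for the former. Counting a gene if any of its probes passed gave 886 genes between the tumours, 255 for the line difference in tumour against flox, 789 between the floxed livers and 1181 among the normal livers.

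Fitting only the groups compared changed the spread estimate: 2875 genes for Sav1 tumour against flox, 4607 for Mst1/2 tumour against flox, 4119 for Mst1/2 surrounding liver against flox, 1049 for Sav1 tumour against surrounding liver, 14 for Mst1/2 tumour against surrounding liver, 91 between the tumours, 363 between the surrounding livers, and 99 and 210 for the line differences against flox. Array weights gave 5688, 3999 and 1255 genes for the 3 Mst1/2 comparisons in that order, 1462 between the tumours, 2537 between the surrounding livers, 1349 between the floxed livers, 1475 among the normal livers, 1038, 1039 and 144 for the 3 line differences and 2855 shared by both tumours.

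With the mean of the 3 normal groups as control, 4253 genes changed in Mst1/2 tumours, 2817 in Sav1 and 1649 in Mst1/2 surrounding liver, and 3421 were shared by both tumours. All 8 normal livers as 1 group, which adds samples, gave 2494 and 1357 genes in the surrounding livers and 3242 shared. Wild-type livers as Mst1/2 control gave 1231 genes in Mst1/2 surrounding liver and the 5 low-Xist livers 1853. With these 2 controls Sult2a2 turned from its fall to 0.20 and 0.31 and Cyp17a1 to 1.04 and 0.53 in that tissue. With the wild-type control, the line difference turned to -0.81 for Cyp17a1 and -0.85 for H2-T10 in tumour against flox, and to -0.091 for Lcn2 and 0 for Hsd3b5 in surrounding liver against flox; that of H2-T10 was -0.19 with the mean of its probes.

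The array set as a block gave 2774 genes for Sav1 tumour and 558 for Sav1 surrounding liver against flox, 18 for Mst1/2 tumour against surrounding liver, 1923 between the tumours, 743 genes and 5 lists between the surrounding livers and 51 for the line difference in tumour against flox. Set A alone gave 948, 21 and 50 genes for Sav1 tumour against flox, surrounding liver against flox and tumour against surrounding liver, set C alone 803 for the last, and set B alone 1705 between the tumours; these fits hold fewer samples.

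The replicate number as a block gave 66 genes for Sav1 tumour against flox, 0 for Sav1 surrounding liver against flox, 0 for Mst1/2 tumour against surrounding liver, 0 between the tumours and 849 between the surrounding livers, and 1364 for Sav1 tumour against surrounding liver, all with limma over the shared numbers, where fewer samples enter. At an unadjusted p under 0.05 the 3 counts of 0 were 2195, 2815 and 1405. Samples of a number deviated together in 5 of 7 pairs of Sav1 tumour and surrounding liver (correlations 0.07 to 0.69, highest for the own number in 4) and in 1 of 3 Mst1/2 pairs, so no pairing was taken there. The block changed no list call between the surrounding livers that had been made without it.

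With an estimated correlation, camera called 0, 4, 0, 1, 1, 2, 0 and 0 lists in the 8 comparisons in the order of the report; where it called 0, 9, 7, 3 and 3 lists had an unadjusted p under 0.05, against 24, 23, 6 and 11 called with the preset correlation. Limma's fry called 27 lists for Sav1 tumour and 17 for Sav1 surrounding liver against flox, 12 for Mst1/2 surrounding liver against flox, 4 for Mst1/2 tumour against surrounding liver, 3 between the tumours and 2 between the surrounding livers.

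Leaving out 1 array at a time gave 2930 to 5076 genes for Sav1 tumour against flox, 1817 to 2526 for Mst1/2 tumour, 307 to 1773 for Sav1 and 184 to 357 for Mst1/2 surrounding liver, 1284 to 2246 for Sav1 and 1 to 88 for Mst1/2 tumour against surrounding liver, 167 to 804 between the tumours, 21 to 173 between the surrounding livers, 222 to 462 between the floxed livers and 1185 to 1857 shared by both tumours; the arrays behind moves over 1.5 times are named with each comparison. The line difference in tumour against flox ran from 79 to 212, with 89 without Sav1 flox 3, 86, 83 and 79 without Mst1/2 flox 4, 5 and 6, and 96 without Mst1/2 tumour 2. In surrounding liver against flox it ran from 39 to 111, with 50 without Sav1 flox 3, 53, 53 and 41 without Mst1/2 flox 4, 5 and 6, and 49, 46 and 39 without Mst1/2 surrounding liver 1, 2 and 3. In tumour against surrounding liver it ran from 4 to 20, with 4 and 5 without Mst1/2 surrounding liver 1 and 2 and 20 without Mst1/2 tumour 3. The count among the normal livers ran from 426 to 944, with 475 without Sav1 flox 3, 466 and 459 without Mst1/2 flox 5 and 6 and 426 without wild-type liver 7.

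With array weights, 280 of 280 results of named genes kept their direction and side of the threshold. Those that no longer passed numbered 1 with the authors' values, 29 with median scaling, 25 with the array set block, 37 in fits of the groups compared, 100 of 160 with the replicate block and 71 of 126 within set A (fewer samples), 33 of 103 with the wild-type control, where 6 more turned, and 283 of 3262 when 1 array was left out.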

Other observations

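The genes and tumours named here were chosen after their values were seen, and the list tests before. Genes that Wnt signalling sustains around the central vein varied widely between tumours. Glutamine synthetase (Glul) ran from 7.29 to 13.63 in log2 signal over the 11 Sav1 tumours, against 8.57 to 9.5 in the 3 Sav1 floxed livers, and the glutamate transporter gene Slc1a2 from 6.24 to 14.91, against 11.44 to 12.27. In the 7 Sav1 surrounding livers Glul ran from 8.23 to 12.42, Slc1a2 from 8.34 to 12.47 and Axin2 from 7.41 to 8.03. Sav1 tumours 3, 6, 8 and 11 had Glul at 12.69, 13.63, 13.23 and 13.03, Slc1a2 at 14.41, 14.91, 14.17 and 12.60, the Wnt feedback gene Axin2 at 10.49, 9.40, 10.08 and 9.23 and the Wnt target Sp5 at 12.03, 11.97, 11.59 and 10.80, where the floxed livers reached at most 8.29 for Axin2 and 8.67 for Sp5. Tumours 1 and 2 had Axin2 at 9.25 and 8.70 and Sp5 at 10.14 and 10.43 beside Glul at 7.29 and 7.83. Tumours 4, 5, 7, 9 and 10 had Axin2 from 6.43 to 6.63. Among the 4 Mst1/2 tumours, tumour 3 had Glul at 11.82, Axin2 at 9.67 and Sp5 at 11.10, and the others had 7.23 to 7.70, 6.12 to 7.35 and 6.28 to 7.25. No test across these tumours was made. Set A holds Sav1 tumours 1 to 3 and set C tumours 4 and 5, so set and this difference are not separated there. Set B holds both kinds. Within set A the pericentral list was called higher in Sav1 tumours against flox (4 of 17 rose), where over all arrays 1 rose, 1 fell and it was not called.

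In Mst1/2 tumours against floxed livers, among pericentral Wnt-responsive genes 1 of 17 rose, 2 fell and 14 did not pass (1 rose and 3 fell adjusted over the list alone, camera lower, adjusted p = 0.040, p = 0.61 with estimated correlation), with a median of -1.32, and in the surrounding livers 17 did not pass (camera adjusted p = 0.026, p = 0.59 with estimated correlation), with a median of -1.29. Against the wild-type livers the medians were -0.74 and -0.62, and neither list was called. The 3 surrounding livers had Slc1a2 at 7.10, 6.18 and 8.04, against 12.13 to 12.60 in the floxed livers.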
